A study of Homo sapiens with 12 samples.

How the data were processed

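HL-60 is an established human promyelocytic leukemia line that matures toward neutrophil-like cells when grown with dimethyl sulfoxide (DMSO). Per the labels, cells were left undifferentiated or were treated with 1.5% DMSO (211 mM) for 7 days, and viable cells were sorted as negative (undifferentiated) or positive (differentiated) for CD11b, the product of ITGAM. DNA of 3 biological replicates per state was sheared and each preparation was shared out between an antibody against 5-methylcytosine (5mC; methylated DNA immunoprecipitation, MeDIP) and an antibody against 5-hydroxymethylcytosine (5hmC; hMeDIP), so that 12 libraries were sequenced. Antibody capture measures how much DNA carrying a mark was pulled down, not the percentage of modified cytosines, and it also depends on CpG density and on how many copies of a locus the cells hold. No input or control-antibody library was analysed here. Because the sort was made on CD11b, the comparison of the states is a comparison of sorted fractions.

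The submitters' processing notes name BWA (version not given), SAMtools 0.1.18, bedtools 2.17.0, SICER 1.1 and edgeR 2.11 with the genome GRCh37 (hg19), without a role for each. The deposited data hold a table for each mark, which lists enriched regions whose edges lie on a 200-base grid, each with read counts for the 6 libraries of that mark, and these counts were deposited unnormalized. The authors also deposited an edgeR log2 fold change and a mean log2 CPM (counts scaled to a common library total) per region; from the counts, the sign of the deposited log2 fold change is undifferentiated over differentiated. The deposited tables give the authors' p-value and adjusted p-value for each region. Distances to the nearest gene, to the start of a gene and to a CpG island are given per the file headers; the annotation they were taken from is not given in the sources used here. Whether regions were called in single or pooled libraries is not given in the sources used here.

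The 5hmC table listed 327949 regions, of which 18 had no values and were left out. The 5mC table listed 65535 regions and held only the most significant ones: in the authors' deposited table the largest p-value was 0.0165 and the largest adjusted p-value 0.0826, which together imply 328588 tested regions. The 5mC results therefore concern a list that was already chosen for a difference between the states, the share of listed 5mC regions that passed has no meaning for the genome, and the sums of listed counts are not the depth of the MeDIP libraries. For the same reason p-values of 5mC regions were adjusted over the implied number of tests. This corrects the number of tests only. The spread was estimated from the selected regions alone, so the p-values of 5mC regions can still be too small. P-values of 5mC genes were adjusted over the 12637 genes tested and carry no correction for the selection. Gene names that a spreadsheet had turned into dates were found for 82 of the listed 5mC and 508 of the listed 5hmC regions and were not matched to genes.

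Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8). For each mark the 3 differentiated libraries were compared with the 3 undifferentiated ones by edgeR's quasi-likelihood F test after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values given for regions and genes are from this test with n = 3 per state unless another test is named. Log2 fold changes are differentiated over undifferentiated, and their standard errors (SE) were taken from the fold change and the F statistic. For values per gene, counts were summed over all regions in the gene body or within 5 kb upstream of its start, as the deposited distances place them; a region near several genes counted for each. Region and gene tests estimate their spread separately, so a gene with 1 region can pass at gene level and its region not. Regions were also classed as promoter (within 1 kb of a gene start by the deposited distance), gene body or intergenic. They were classed too as CpG island, island shore (within 2 kb) or neither. Exons and introns were not told apart because no annotation of this build was used here. The deposited distance was read as one upstream of a start. Regions inside genes could lie far from any such start, as in THBS2 (458858 bases). The promoter class and counts within 2 kb of gene starts may therefore leave out regions just downstream of a start. Shares of classes carry 95% exact binomial intervals, which cover counting error only, and were compared by Fisher's exact test (two-sided).

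In all, 20 gene lists holding 595 genes were fixed for lineage markers, HOX clusters, DNA methylation enzymes, the cell cycle, the neighbourhood of MYC and signaling pathways. By symbol, 544 of these genes were matched in the 5hmC gene table and 356 in the 5mC gene table; older symbols of the GRCh38.p14 RefSeq gene table added none. Each list with 5 or more tested members was tested with camera at a preset inter-gene correlation of 0.01 on log2 CPM, again with an estimated correlation, and with fry, and adjusted over the 20 lists. Shares of counts per chromosome were compared by exact two-sided permutation tests, for which 3 against 3 libraries can give no p under 0.1. Count densities were described in 1 Mb windows relative to the median window. The marks were compared by correlations of their log2 fold changes across genes and across regions overlapping by at least 1 base; genes and regions are not independent replicates.

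Named regions were, for each mark, the 10 higher and 10 lower with the largest change among those that passed, had a mean count of 10 or more and had all 3 libraries of a state above all 3 of the other, with 1 region per gene. Of each list, up to 3 members with the smallest adjusted p were named, and ITGAM, MPO, MYC, CEBPE, TET2, DNMT3A, DNMT1 and CSF3R were always named. Some genes and regions that the rule names, and 1 gene list, are not reported here. The grouping, tests, lists, naming rule and the following alternatives were chosen before the data were examined. These alternatives were DESeq2 size factors, library totals without TMM, the DESeq2 Wald test, no filter, a threshold of 0.01, a replicate block, leaving out each library, counts within 2 kb of gene starts only, chromosome shares below the 99th percentile of counts, 5 Mb windows, and a stricter overlap rule (0.5 of the smaller region). Added after the data had been seen were TMM on strong regions only (deposited log2 CPM above 2), totals of regions below the 99th percentile, the other scalings and left-out libraries for the gene lists, and adjustment over listed 5mC regions only.

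The tests were tested on simulated data with 50 rows changed at each fold. Of 5hmC regions, 2% changed 1.5-fold, 56% changed 2-fold, 92% changed 3-fold and 100% changed 4-fold were recovered, with 3 false calls in all; of 5mC regions these shares were 38%, 82%, 94% and 96%, with 8 false calls. At gene level they were 78%, 98%, 100% and 100% for 5hmC (12 false calls) and 72%, 94%, 100% and 100% for 5mC (7 false calls). When simulated 5hmC regions were reduced to the 65535 with the smallest p and refitted, 4%, 58%, 96% and 98% were recovered, with 8 false calls. The simulated regions had no spread of their own beyond a trend with the count level. This simulation therefore could not show the effect of selecting regions with little spread. Of 100 simulated lists without a change, camera gave 2% a p under 0.05, and it found 20 of 20 lists shifted 1.3-fold. With so few changed rows the adjustment is stricter than in data with many changes, so these shares describe sparse changes only.

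Fold changes computed here were compared with those of the authors' deposited table: across regions they correlated at r = 1 for 5mC and 0.9994 for 5hmC, with median absolute differences of 0.00314 and 0.0147 log2. At its adjusted p of 0.05 the authors' deposited table called 48984 5mC regions (24165 higher and 24819 lower in differentiated cells) and 148664 5hmC regions (84014 higher and 64650 lower).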

Results

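HL-60 promyelocytic leukemia cells were compared before and after differentiation with DMSO toward neutrophil-like cells. The question was how 5mC and 5hmC differ between the states, which signaling genes carry the differences, and which chromosome segments stand out as amplified. Each state had 3 biological replicates, and each replicate gave 1 library per mark, 12 in all. The 5hmC regions held 33693880, 18886675 and 15688562 counts in undifferentiated replicates 1, 2 and 3. In differentiated replicates 1, 2 and 3 they held 18988574, 13010267 and 32495733. The listed 5mC regions held 6851769, 6076100 and 6306580 counts in undifferentiated and 9598834, 7940755 and 9670011 in differentiated replicates. These 5mC totals are not the depth of the libraries, because the list was already selected. Regions of 5hmC had a median width of 600 bases (200 to 481400) and covered 269.2 Mb. Those of 5mC had a median width of 800 bases (200 to 331200) and covered 71.28 Mb. Across 5hmC regions, log CPM (counts scaled to a common library total) correlated at 0.893 to 0.925 between undifferentiated libraries, at 0.882 to 0.934 between differentiated libraries and at 0.725 to 0.776 between the states. Across the selected 5mC regions these correlations were 0.935 to 0.938, 0.957 to 0.96 and 0.793 to 0.817.

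The 5hmC regions with the largest rises, among those named by the rule, lay inside CNTN5, which encodes a contactin of neurons, and LPCAT1, which encodes an enzyme of phospholipid remodeling. The CNTN5 region (chromosome 11, 99782801 to 99783200, hg19) rose from 0.262 ± 0.034 to 1.48 ± 0.457 CPM (SD, n = 3 per state), a log2 fold change of 2.38 (SE 0.357, adjusted p = 1.54e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The LPCAT1 region (chromosome 5, 1513201 to 1514200) rose by 2.30 on the log2 scale (SE 0.271, adjusted p = 2.04e-08 by the same test). Rises of 1.99 to 2.22 were found in regions within IL18BP and RNF121, LINC00669, CNBD1, DCC, IGSF21, SHISA9, NAA30 and GUCY1A2. DCC encodes a netrin receptor and IL18BP a secreted inhibitor of interleukin 18. The largest falls lay inside CSMD1, which encodes a complement regulator (chromosome 8, 4185601 to 4186000, log2 fold change −2.48, SE 0.434, adjusted p = 1.81e-05), and CALN1, which encodes a calcium-binding protein (−2.26, SE 0.389). Log2 fold changes of −2.10 to −1.96 were found for AP5S1, ANKRD6, CCPG1, ATP8A1, COL5A2, MMS22L, UCHL5 and MERTK, the last encoding a receptor with which macrophages take up dying cells. Of these 20 regions, that of AP5S1 lay 2172 bases upstream of the gene start and the others lay in gene bodies. In all, 88587 regions rose and 76317 fell among 327901 tested, so that 53.7% of the called regions were higher, and the median absolute log2 fold change of called regions was 0.727. The libraries of the states did not overlap in 52.2% of the tested regions, where chance gives 10%. Scaled by library totals without TMM, 46026 rose and 118325 fell (28% higher), and with TMM on strong regions only 18.4% of 167050 were higher. DESeq2's Wald test called 66484 regions (65.0% higher). Leaving out undifferentiated replicate 1 or differentiated replicate 3 lowered the edgeR count to 102884 or 105251.

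At gene level, 5hmC rose at 5251 and fell at 5272 of 20404 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 3 per state). Without TMM 1591 genes were higher and 8545 lower, and with TMM on strong regions 837 were higher and 10633 lower. MPO, which encodes the myeloperoxidase of primary granules, fell from 7.16 ± 0.978 to 3.97 ± 0.389 CPM (SD), a log2 fold change of −0.84 (SE 0.132, adjusted p = 0.000239). Of 18 tested primary granule and progenitor genes, 6 fell and 1 rose. Among those that fell were NUCB2, which encodes a calcium-binding nucleobindin (−0.48), and TFRC, the transferrin receptor gene, which is also in the erythroid list (−0.59). Of 33 neutrophil maturation genes, 10 rose and 4 fell. The surface antigen gene CD177 rose (0.30, SE 0.0694), and LYZ, which encodes lysozyme, fell (−0.64, SE 0.136). ITGAM, whose product CD11b the cells were sorted on, rose by 0.17 (SE 0.0609, adjusted p = 0.033). Its call ended without undifferentiated replicate 1 (0.14) or 3 (0.16), without differentiated replicate 1 (0.16) and in DESeq2's Wald test (0.18). Its sign turned without TMM (−0.04), with TMM on strong regions (−0.13) and within 2 kb of its start (−0.56). CSF3R, the receptor gene of granulocyte colony-stimulating factor (−0.09, adjusted p = 0.282), and CEBPE, which encodes a transcription factor of late granulocyte maturation (0.04, adjusted p = 0.891), did not pass. CSF3R passed as lower without TMM (−0.28). Of 31 myeloid transcription factor genes, 9 rose and 4 fell. Rises lay at RARA, the retinoic acid receptor alpha gene (0.42), IKZF1, which encodes Ikaros (0.60), and RUNX1, a regulator of blood cell formation (0.31). Of 18 monocyte and macrophage genes, 7 rose and 1 fell. The scavenger receptor gene MARCO (0.56) and the Fc receptor gene FCGR1A (0.64) rose, and the fatty acid transporter gene CD36 fell (−0.64). FCGR1A no longer passed without undifferentiated replicate 1 (0.58).

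Among lists of other blood lineages, 8 of 20 erythroid and megakaryocyte genes gained 5hmC and 2 lost it. Rises lay at ALAS2, which encodes an enzyme of heme synthesis (0.84, SE 0.0949, n = 3 per state), and ANK1, which encodes ankyrin of the red cell membrane (0.32). Of 26 lymphoid genes, 9 rose and 1 fell, with rises at the B-cell genes PAX5 (0.29) and BLK (0.36) and at NCAM1, which encodes CD56 (0.28). With TMM on strong regions PAX5 (−0.0049) and NCAM1 (−0.02) turned. Of 12 eosinophil and basophil genes, 5 rose and 2 fell: the eotaxin receptor gene CCR3 (0.32) and the transcription factor gene GATA1 (0.41) rose, and MS4A2, which encodes an IgE receptor chain, fell (−0.69). The rises in the lineage lists were relative to the scaling, which moved the median of all genes to −0.19 without TMM and to −0.28 with TMM on strong regions. Without TMM, 1 neutrophil gene was higher and 10 were lower, 0 lymphoid genes were higher and 7 lower, and 1 eosinophil gene was higher and 5 were lower. In the same scaling 4 erythroid genes were higher and 7 lower, 3 transcription factor genes were higher and 7 lower, and 2 monocyte genes were higher and 2 lower. In each of these scalings, which move all genes down alike, 12 primary granule genes were lower and 0 higher. By camera, adjusted over the 20 lists, none of these 7 lists passed: transcription factors and monocyte genes had an adjusted p of 0.15, lymphoid genes 0.185, erythroid genes 0.224, primary granule genes 0.239, neutrophil genes 0.407 and eosinophil genes 0.776.

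Of 39 genes in the HOX clusters, which encode transcription factors of body axis and blood progenitors, 31 were tested; 15 gained 5hmC, 3 lost it and 13 did not pass. HOXC9 rose from 3.71 ± 0.495 to 7.37 ± 0.643 CPM (log2 fold change 0.96, SE 0.127, adjusted p = 8.05e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per state), HOXA6 rose by 0.78 (SE 0.145) and HOXB3 by 0.47 (SE 0.0647). The HOX list was higher than other genes by camera (median log2 fold change 0.27, adjusted p = 0.0294; adjusted p = 0.376 with an estimated correlation; adjusted p = 0.0545 without differentiated replicate 3). It passed upward without TMM too, though with 8 genes higher and 3 lower, and with TMM on strong regions, with 4 higher and 4 lower. Of the regions counted for HOX genes, 35.8% lay in CpG islands, against 1.73% of all 5hmC regions. Island regions had a median of 0.38 under TMM scaling. The HOX list was not compared with island regions of other genes, so a change particular to HOX genes was not shown. Of 37 calcium and phospholipase genes, 16 rose and 3 fell: the calcium channel genes CACNA1E (0.37, SE 0.0556) and CACNA1C (0.35, SE 0.054) rose, and ATP2A2, which encodes the calcium pump of the endoplasmic reticulum, fell (−0.51, SE 0.062). This list passed as higher (median 0.12, adjusted p = 0.0294), but not with an estimated correlation (adjusted p = 0.376), without undifferentiated replicate 1 (0.0517) or 2 (0.0677) or without TMM (0.409; 3 genes higher, 11 lower). With TMM on strong regions its direction turned, with 0 genes higher and 17 lower. No list passed with an estimated correlation.

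Of 26 MYC and cell-cycle genes, 9 lost 5hmC and 0 gained it: PCNA, which encodes the replication clamp, fell by 0.76 on the log2 scale (SE 0.119, n = 3 per state). MDM2, which encodes a ligase of p53, fell by 0.73 (SE 0.083) and the cyclin D3 gene CCND3 by 0.41. MYC itself fell from 697 ± 26.1 to 530 ± 67 CPM (−0.40, SE 0.0765, adjusted p = 0.000967 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), although its only region did not pass as a region (−0.38, adjusted p = 0.213). MYC is also in the list of its 8q24 neighbours, of which 6 fell and 2 rose among 19 tested. NSMCE2, which encodes a SUMO ligase, fell (−0.49), as did TATDN1 (−0.41), and ADCY8, an adenylate cyclase gene, rose (0.34). Of 22 genes for DNA methylation and its removal, 10 fell and 3 rose. The maintenance methyltransferase gene DNMT1 fell from 46.9 ± 0.289 to 35.6 ± 1.32 CPM (−0.40, SE 0.0522, adjusted p = 6.86e-05), UHRF1, whose product recruits it, fell by 0.34, and the methyl-CpG binding gene MBD1 rose by 0.58. TET2, which encodes an enzyme that makes 5hmC from 5mC, fell by 0.24 (SE 0.0645, adjusted p = 0.00686; not past the threshold at −0.20 without undifferentiated replicate 1 or at −0.23 in DESeq2's Wald test). The de novo methyltransferase gene DNMT3A did not pass (0.11, adjusted p = 0.115). It passed as higher without undifferentiated replicate 2 (0.16) or differentiated replicate 2 (0.13), and was lower with TMM on strong regions (−0.18). By camera the adjusted p was 0.0846 for MYC and cell-cycle genes, 0.197 for DNA methylation genes and 0.776 for the 8q24 list.

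Of 28 PI3K, AKT and mTOR genes, 14 lost 5hmC and 5 gained it. The S6 kinase gene RPS6KB1 fell from 40.6 ± 0.51 to 26.2 ± 0.969 CPM (log2 fold change −0.63, SE 0.0539, adjusted p = 1.73e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per state). The kinase gene PIK3CD (−0.38) and EIF4EBP1, which encodes a translation repressor (−0.48; 0.02 within 2 kb of its start), fell as well. This list did not pass (adjusted p = 0.0846) but was lower without TMM (0.0241) and with TMM on strong regions (0.00931). Of 36 MAPK genes, 12 fell and 5 rose, with a fall at the exchange factor gene SOS2 (−0.41). Of 29 JAK-STAT and cytokine genes, 10 fell and 8 rose, with falls at STAT3 (−0.49), the interferon gamma receptor gene IFNGR2 (−0.51) and IL6ST, which encodes the shared receptor chain gp130 (−0.73). WASF2, which encodes a regulator of the actin skeleton, fell (−0.44; 0.0087 within 2 kb of its start). Of 41 Wnt genes, 12 rose and 5 fell, with rises at the ligand genes WNT7A (0.63) and WNT5A (0.75) and at the inhibitor gene DKK2 (0.48; −0.22 within 2 kb of its start). Of 23 NF-kB and toll-like receptor genes, 6 rose and 5 fell, with a rise at the inhibitor gene NFKBIE (0.45) and falls at IRAK2 (−0.37) and RELB (−0.27). Of 26 Notch genes, 7 rose and 5 fell, with a rise at the glycosyltransferase gene MFNG (0.26; −0.03 with TMM on strong regions) and falls at the Notch antagonist gene NUMB (−0.47) and the coactivator gene MAML1 (−0.37). Of 29 TGF-beta and BMP genes, 7 rose and 6 fell, with a rise at the receptor gene BMPR1B (0.34) and falls at BMPR2 (−0.35) and the corepressor gene SKIL (−0.54). Without TMM more genes were lower than higher in each of these lists, with 3 higher and 12 lower Wnt genes, 2 and 12 Notch genes, 0 and 9 NF-kB genes and 0 and 12 TGF-beta genes. None of these lists passed either: adjusted p was 0.197 for Wnt, 0.407 for MAPK, 0.621 for JAK-STAT, 0.807 for TGF-beta, and 0.868 for NF-kB and Notch genes. By fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, 14 of the 20 lists passed for 5hmC. Among them were Wnt (adjusted p = 0.00151), JAK-STAT (0.00984) and MAPK genes (0.011), and not among them were the 8q24 (0.437), eosinophil (0.128), TGF-beta (0.921), NF-kB (0.796) and Notch lists (0.74). Adjusted over the list alone, the counts were those given except for 16 higher HOX genes, 8 higher transcription factor genes, 8 higher lymphoid genes and 8 lower cell-cycle genes. Of the 5hmC genes named as higher, ADCY8, ANK1, BLK, BMPR1B, CCR3, CD177, MFNG, NCAM1, NFKBIE, PAX5 and RUNX1 did not pass without TMM. With TMM on strong regions, CACNA1C, CACNA1E, DKK2, FCGR1A, GATA1, HOXB3 and RARA did not pass either. Within 2 kb of gene starts, CACNA1C (0.11), CACNA1E (0.13), CD177, IFNGR2, RELB, SKIL, STAT3 and TFRC did not pass for 5hmC.

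**Figure D1:**
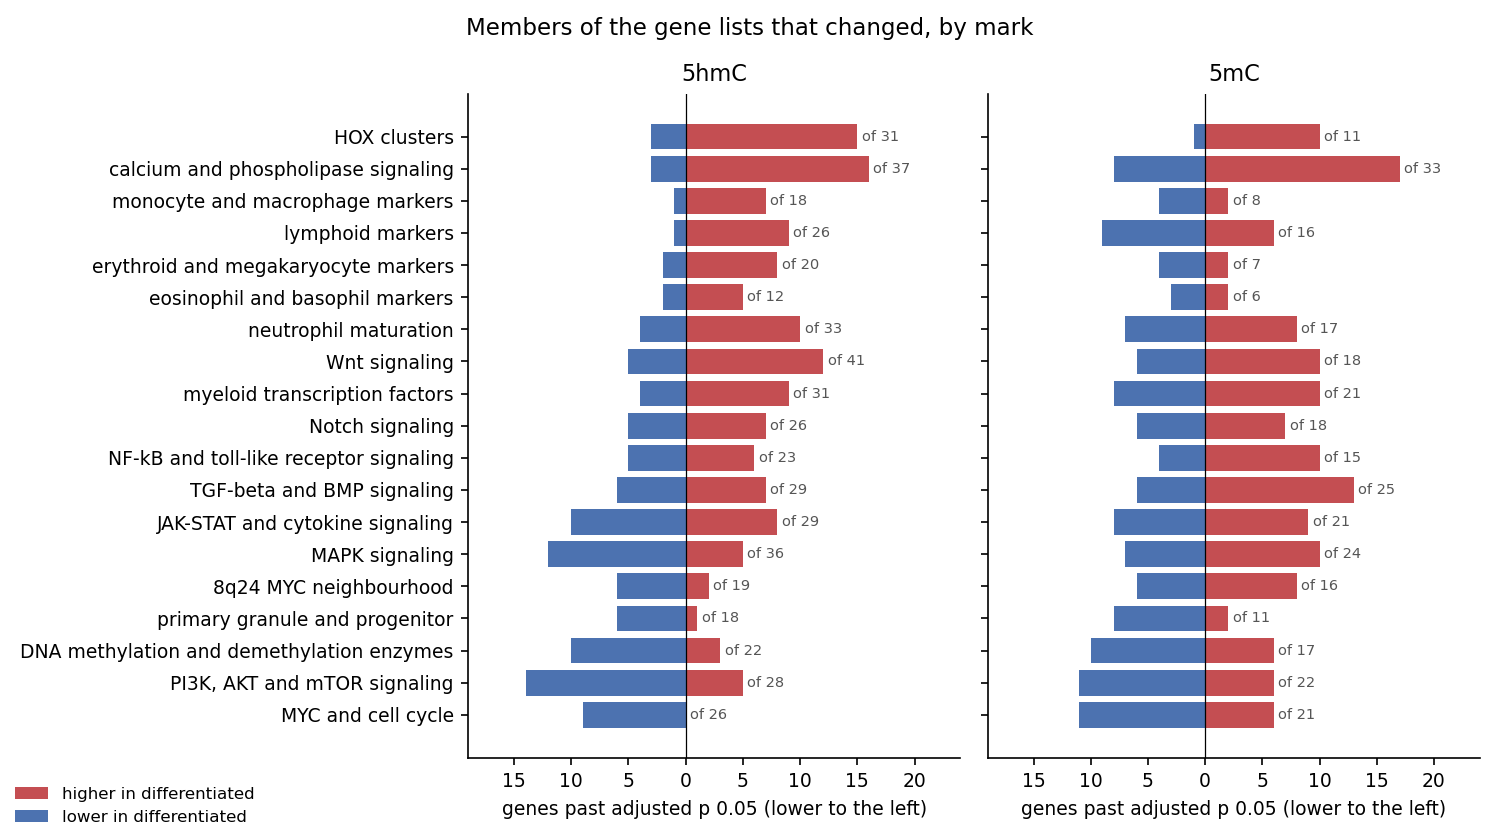
Members of 19 gene lists with higher (right) or lower (left) 5hmC or 5mC in differentiated cells at an adjusted p of 0.05 (edgeR, TMM scaling, 3 libraries per state), with the number tested beside each bar. For 5hmC, MYC and cell-cycle genes had 0 higher and 9 lower and HOX genes 15 higher and 3 lower; without TMM no list had more higher genes than this, and calcium genes had 3 higher and 11 lower.

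The selected 5mC regions with the largest rises lay in TAF4B, which encodes a gonadal subunit of a transcription factor complex, and WFIKKN1, which encodes a secreted binder of growth factors. The TAF4B region (chromosome 18, 23883001 to 23883600) rose from 0.94 ± 0.583 to 4.35 ± 0.757 CPM (SD, n = 3 per state), a log2 fold change of 2.16 (SE 0.323, adjusted p = 3.88e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the implied number of tests). A region in THBS2, a thrombospondin gene (chromosome 6, 169642601 to 169643400), rose by 1.57 (SE 0.205, adjusted p = 3.75e-09). A region 2088 bases upstream of CD83, which encodes a marker of mature dendritic cells (chromosome 6, 14115001 to 14115400), rose by 1.52 (SE 0.314). Other rises, of 1.51 to 1.68, lay in WFIKKN1, NPSR1-AS1, DLGAP2, DOCK1 and PTPRT. The largest fall lay in the Wnt ligand gene WNT9B (chromosome 17, 44948001 to 44948400), from 3.55 ± 0.859 to 0.921 ± 0.541 CPM (−1.97, SE 0.345, adjusted p = 2e-05). Log2 fold changes of −1.93 to −1.71 were found in MKL1, which encodes a coactivator of actin-regulated genes, and in FBXL2, SMG5, MYLK-AS1, FAM168A, SLTM, SRRM4, GRIK1 and AGAP6. In all, 23375 listed 5mC regions were higher and 24287 lower (49.0% of called regions higher), with a median absolute log2 fold change of 0.646. The states did not overlap in 86.1% of the listed regions, where chance gives 10% in an unselected list. Without TMM 2494 were higher and 32689 lower (7.09% higher), with TMM on strong regions 5.03% of 34422 were higher, and with totals of regions below the 99th percentile 33.2% of 46313. The authors' fold changes lay a median of 0.00314 log2 from those under TMM, and their p-values selected the list. Regions that only another scaling would call are therefore missing. Library totals of 5mC were sums of listed counts. The 5mC balances under other scalings, for regions and genes, are thus partly set by the selection. DESeq2's Wald test, with the same adjustment, called 3408, and leaving out any 1 library left 29074 to 30539.

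At gene level, listed 5mC was higher at 5184 and lower at 5461 of 12637 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over these genes (n = 3 per state). These genes hold only regions selected for a difference, and 84.2% of them passed. Their p-values carry no correction for that selection. Without TMM 1405 genes were higher and 6835 lower, and with TMM on strong regions 1010 were higher and 7042 lower. MPO fell from 11.5 ± 1.5 to 7.20 ± 1.76 CPM (−0.65, SE 0.155, adjusted p = 0.000186), and of 11 primary granule and progenitor genes 8 fell, TFRC (−0.81) and NUCB2 (−0.69) among them, and 2 rose. Of 17 neutrophil maturation genes, 8 rose and 7 fell. Rises lay at ALOX5, which encodes a leukotriene-forming enzyme (1.04, SE 0.184), and NCF4, which encodes a subunit of the NADPH oxidase (0.67), and the chemokine receptor gene CXCR2 fell (−1.07, SE 0.25). ITGAM rose by 0.16 (SE 0.0513, adjusted p = 0.00427) but was lower without TMM (−0.15), with TMM on strong regions (−0.19) and within 2 kb of its start (−0.68). CSF3R rose by 0.49 (SE 0.157, adjusted p = 0.00434); it did not pass without differentiated replicate 3 (0.33) or without TMM. CEBPE had no listed 5mC region. Of 21 myeloid transcription factor genes, 10 rose and 8 fell, with rises at IRF4 (0.60) and at MEIS1, which encodes a partner of HOX proteins (0.88). Of 8 monocyte and macrophage genes, 4 fell and 2 rose: the costimulator gene CD86 fell (−1.10), as did the integrin gene ITGAX (−0.71), and the complement gene C1QB rose (0.77). Of 7 erythroid and megakaryocyte genes, 4 fell, SLC4A1, the anion exchanger of red cells, among them (−0.46), and 2 rose, with ANK1 at 0.38. Of 16 lymphoid genes, 9 fell and 6 rose, with rises at the T-cell genes BCL11B (0.46) and CD8B (0.58) and the B-cell gene EBF1 (0.41). Of 6 eosinophil and basophil genes, 3 fell and 2 rose. PRG3, a granule protein gene, fell (−0.73), and CCR3 (0.58) and the receptor gene SIGLEC8 (0.47; 0.34 and not past the threshold without undifferentiated replicate 3) rose.

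Of 11 HOX genes with listed 5mC regions, 10 rose and 1 fell. Of the regions counted for them, 61.5% lay in CpG islands, against 2.35% of all listed 5mC regions. Some neighbouring genes were counted with the same values, such as HOXB6 and HOXB7 (0.33 each). HOXA5 and HOXA6, which share 1 region, rose by 0.44 (SE 0.0721, adjusted p = 2.73e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per state) and HOXA3 by 0.38 (−0.63 within 2 kb of its start). Of 33 calcium and phospholipase genes, 17 rose and 8 fell, with rises at CACNA1C (0.40), the protein kinase C gene PRKCA (0.44) and NFATC1, which encodes a transcription factor driven by calcium (0.32; −0.03 with TMM on strong regions). Of 17 DNA methylation genes, 10 fell and 6 rose. TET2 fell from 18.9 ± 1.08 to 11.4 ± 0.446 CPM (−0.73, SE 0.119, adjusted p = 1.71e-07). TET1 (−0.74) and DNMT3B (−0.42) fell, and DNMT3A rose (0.33, SE 0.0501; 0.02 and not past the threshold without TMM, −0.02 with TMM on strong regions). DNMT1 did not pass (−0.08, adjusted p = 0.463) but fell without TMM (−0.38). Of 21 MYC and cell-cycle genes, 11 fell, MYC (−0.49, SE 0.0343) and CCND3 (−0.43) among them, and 6 rose, among them MKI67, which encodes the proliferation marker Ki-67 (0.49). Of 22 PI3K, AKT and mTOR genes, 11 fell, with MTOR at −0.35 and PIK3CD at −0.40, and 6 rose, with RPTOR at 0.38. Of 24 MAPK genes, 10 rose, with the kinase gene RPS6KA2 at 0.39, and 7 fell, with SOS1 at −0.60. Of 21 JAK-STAT genes, 9 rose, with the kinase gene JAK1 at 0.58, and 8 fell, with STAT3 at −0.54 and STAT5B at −0.87.

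Of 15 NF-kB genes with listed 5mC regions, 10 rose and 4 fell, with rises at the flagellin receptor gene TLR5 (0.75, SE 0.148, n = 3 per state), the kinase gene IKBKB (0.50) and the adaptor gene TRAF2 (0.38). Of 18 Wnt genes, 10 rose and 6 fell, with rises at WNT7B (1.05, SE 0.207), DKK2 (0.65) and the transcription factor gene TCF7L2 (0.55). Of 25 TGF-beta genes, 13 rose and 6 fell, with rises at BMPR1B (0.60) and the ubiquitin ligase gene SMURF1 (0.71) and a fall at its relative SMURF2 (−0.85). Of 18 Notch genes, 7 rose and 6 fell: the ligand gene JAG1 rose (0.53), and ADAM10, which encodes a protease that cleaves Notch, fell (−0.42). Of 16 genes around MYC on 8q24, 8 rose and 6 fell, with falls at NSMCE2 (−0.52) and TRIB1 (−0.50), a pseudokinase gene, which share a region. Scaling moved the median of all 5mC genes to −0.31 without TMM and to −0.34 with TMM on strong regions. Without TMM 0 HOX genes rose and 1 fell, and more genes were lower than higher in every list. By camera no list passed: adjusted p was 0.102 for HOX and for calcium genes, 0.485 for primary granule genes, 0.993 for lymphoid, Notch and eosinophil genes, and 0.817 for 13 other lists. By fry 10 of the 20 lists passed for 5mC, among them HOX and calcium genes (adjusted p = 0.00243 each). Fry does not compare a list with other genes, and only regions selected for a difference between the states entered. The 5mC results of fry and the counts of changed members are therefore partly set by the selection and are no support on their own. Camera pointed down for the 8q24 list, whose median (0.21) and mean (0.087) lay above 0, and for Notch genes, with a median of −0.0017 and a mean of 0.0089. Adjusted over the list alone, the counts were those given except for 7 higher lymphoid genes. Of the 5mC genes named as higher, ANK1, CSF3R, DNMT3A, EBF1, HOXA3, HOXA5, HOXA6, IKBKB, NFATC1, RPTOR, SIGLEC8 and TRAF2 did not pass without TMM. With TMM on strong regions, BCL11B, CACNA1C, CD8B, MEIS1, MKI67 and RPS6KA2 did not pass either. Within 2 kb of gene starts, SIGLEC8 and SMURF1 did not pass for 5mC.

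Under TMM scaling, CpG island regions were mostly higher in differentiated cells for both marks. For 5hmC, 2391 island regions rose and 214 fell among 5675 tested. Of the called ones 91.8% were higher (95% exact binomial interval 90.7 to 92.8, odds ratio against other called regions 9.86). For 5mC, 1089 listed island regions were higher and 134 lower among 1541 (89.0%, 87.2 to 90.7; odds ratio 8.81, two-sided Fisher's exact p = 3.93e-199). Regions are not independent replicates, so the intervals cover counting error only. Island medians were 0.38 for 5hmC and 0.39 for 5mC on the log2 scale, against −0.04 and 0.22 for all regions. Promoter regions were higher in 65.2% of called 5hmC regions (3006 rose, 1603 fell) and in 62.2% of called 5mC regions (892 and 541), and gene bodies in 48.8% and 45.3%. Intergenic regions were higher in 57.4% and 51.9%, and island shores in 49.6% and 49.7%. Without TMM, 1005 5hmC island regions were higher and 467 lower, and for 5mC the balance turned, with 82 higher and 172 lower. Because the 5mC list was selected under a scaling close to TMM, its balance under other scalings is partly set by the selection. Leaving out 1 library gave 721 to 808 higher 5mC islands and 1491 to 2620 higher 5hmC islands. It lowered the count of lower 5mC islands to 80 to 95 and that of lower 5hmC islands to 111 without undifferentiated replicate 1. With TMM on strong regions the balance was lost for 5hmC (610 higher, 614 lower) and turned for 5mC (42 higher, 173 lower). With totals of regions below the 99th percentile it stayed, with 1842 higher and 303 lower for 5hmC and 703 higher and 169 lower for 5mC.

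**Figure D2:**
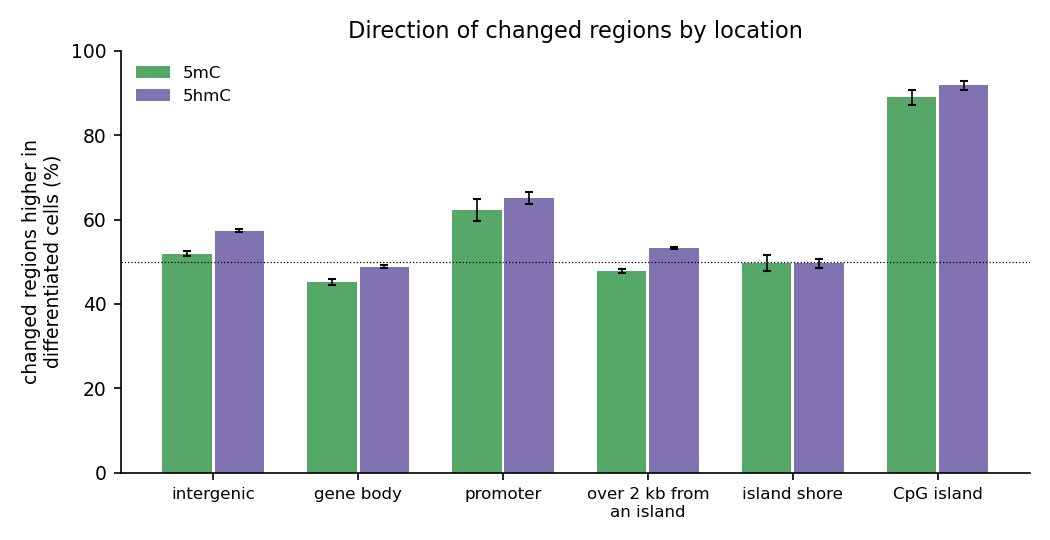
Percent of called regions that were higher in differentiated cells, by location, for 5mC and 5hmC under TMM scaling, with 95% exact binomial intervals. CpG islands stand at 89.0% (5mC) and 91.8% (5hmC) and gene bodies at 45.3% and 48.8%. Without TMM 82 5mC island regions were called higher and 172 lower, and 1005 5hmC island regions higher and 467 lower. The 5mC list was selected under a scaling close to TMM, which partly sets its counts.

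A set of long regions around MYC at 8q24 lost signal in differentiated cells. On chromosome 8, 21 listed 5mC regions of 20 kb or more lay between 126224401 and 130698200, covering 1859.6 kb with 1 region of 331.2 kb. All 21 fell, with log2 fold changes of −0.64 to −0.33 (median −0.48), and 16 of them passed in DESeq2's Wald test. Together they held 3.47% of listed 5mC counts in undifferentiated and 2.07% in differentiated cells. The region over NSMCE2 (126224401 to 126441600) fell from 7360 ± 241 to 4950 ± 582 CPM (−0.57, SE 0.0513, adjusted p = 2.49e-17 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per state). That over MYC (128689001 to 128772000) fell by 0.54 (SE 0.054, adjusted p = 1.83e-14). The outermost, 130367001 to 130698200, lay 62243 bases from GSDMC, a gasdermin gene, and fell by 0.42. For 5hmC, 9 long regions of this span were all lower (−0.48 to −0.09, median −0.23) and none passed. Of these, 6 passed without TMM, 8 with TMM on strong regions, 2 in DESeq2's Wald test and 3 without differentiated replicate 2. The SEs were 0.235 to 0.341 for 5hmC and 0.0513 to 0.0634 for 5mC, where the spread came from a selected list. The difference in calls between the marks is therefore no measure of a difference in change. Short regions inside the segment had medians of 0.43 for 5mC (65 regions) and 0.05 for 5hmC (382 regions). Long regions elsewhere in the genome were all higher, 31 of 31 for 5mC (median 0.53) and 25 of 25 for 5hmC (median 0.78). Differentiated replicate 1 was the lowest library in both marks, at 19240 CPM against 24020 and 24700 for 5mC and at 8967 against 11890 and 11290 for 5hmC. Without it the median was −0.36 for 5mC and −0.11 for 5hmC, where the highest long region lay at 0.03.

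**Figure D3:**
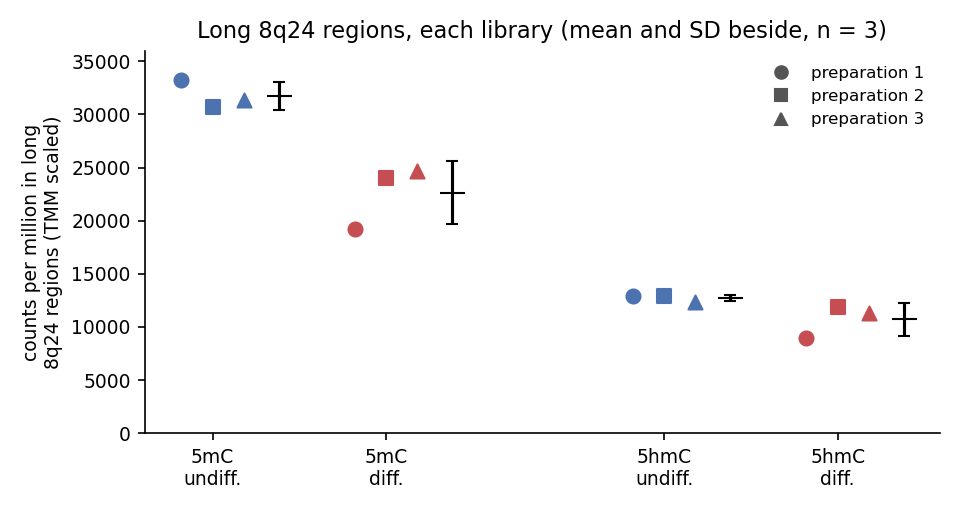
CPM (TMM scaled) summed over the long 8q24 regions in each library, with mean and SD beside the 3 preparations of a state. Undifferentiated 5mC libraries lie at 30700 to 33240 and differentiated ones at 19240 to 24700; for 5hmC they lie at 12350 to 12880 and at 8967 to 11890.

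In 1 Mb windows, the densest 5mC windows lay at pericentromeric repeats: chromosome 16 at 46000001 to 47000000 held 850 times the density of the median window, chromosome 10 at 42000001 to 43000000 held 825 times and chromosome 4 at 49000001 to 50000000 held 486 times. These windows were higher in differentiated cells by 0.49 ± 0.0205, 0.54 ± 0.0265 and 0.64 ± 0.0169 on the log2 scale (SD, n = 3 per state). For 5hmC the densest were the chromosome 4 window (235 times, 0.75 ± 0.208) and a satellite window of chromosome Y at 13000001 to 14000000 (118 times, 0.75 ± 0.212). The mitochondrial genome followed at 96.6 times and 0.43 ± 0.241. As a region it did not pass for 5hmC (adjusted p = 0.504 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). How reads of repeats were placed was not examined, so densities at repeats alone do not show amplified segments. Chromosome Y held 3.07% of listed 5mC counts in undifferentiated cells, but 0.122% below the 99th percentile of counts. Whether its counts came from chromosome Y itself was not tested. On chromosome 8 the windows at 126000001 (88.0 times, −0.50 ± 0.138), 130000001 (62.5 times, −0.46 ± 0.152) and 128000001 (38.7 times, −0.49 ± 0.138) ranked 7, 9 and 12 of 2881 for 5mC. They ranked 10, 13 and 19 of 2908 for 5hmC. Among the 20 densest 5mC windows the only other lower one was chromosome 1 at 1000001 to 2000000 (36.4 times, −0.43 ± 0.0658). Chromosome 8 held 6.76% of listed 5mC counts in undifferentiated and 5.36% in differentiated cells and 5.00% and 4.55% of 5hmC counts. Chromosome 4 rose from 8.37% to 9.98% and from 7.99% to 9.66%. Shares of 22 of 25 chromosomes for 5mC (6 higher, 16 lower) and 23 of 25 for 5hmC (7 higher, 16 lower) were separated between the states at the smallest two-sided exact permutation p that 3 against 3 libraries can give, 0.1 (adjusted p = 0.114 and 0.109), which cannot reach 0.05. Below the 99th percentile of counts the share of chromosome 8 was higher in differentiated cells, by 0.16 for 5mC and 0.069 for 5hmC on the log2 scale. Among called regions, those on chromosome X were higher in 74.2% for 5mC and 72.5% for 5hmC, and those on chromosome 17 in 31.2% and 37.4%.

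**Figure D4:**
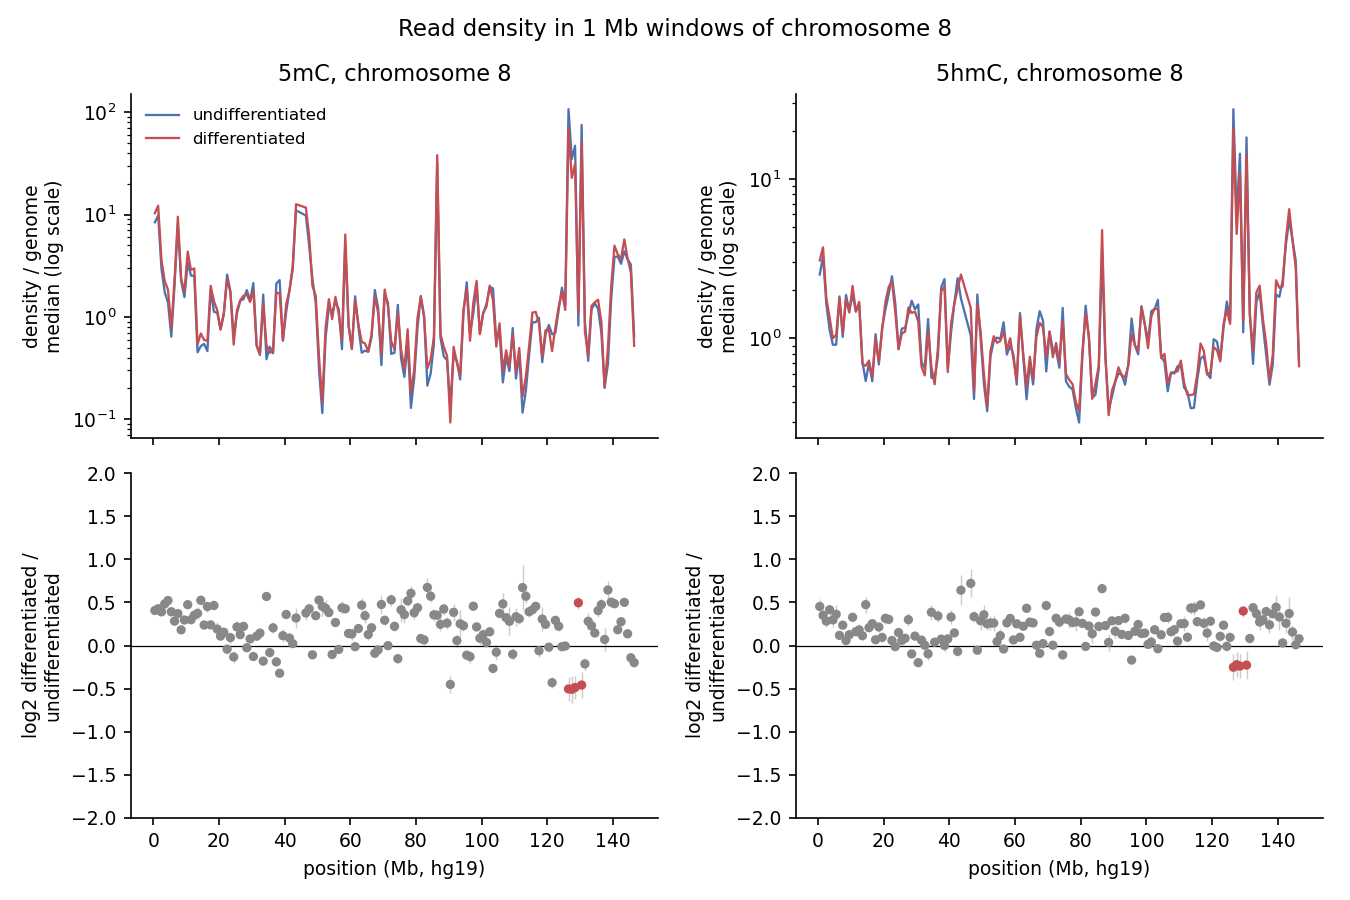
Count density of 5mC (left) and 5hmC (right) in 1 Mb windows of chromosome 8, as a multiple of the median window on a log axis (top), and log2 ratio of differentiated to undifferentiated cells with SD over libraries (bottom; n = 3 per state). The windows marked in red around MYC stand up to 88.0 (5mC) and 23.7 (5hmC) times above the median window, with log2 ratios of −0.50 and −0.25 at 126000001.

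Changes of the marks were compared gene by gene and region by region. MPO, MYC and TET2 fell in both marks and ITGAM rose in both under TMM scaling, though ITGAM was lower in both without TMM (−0.04 for 5hmC, −0.15 for 5mC). DNMT1 fell in 5hmC alone and DNMT3A and CSF3R rose in 5mC alone; whether the marks differed at these genes was not tested. Across 12329 genes the log2 fold changes correlated at Pearson r = 0.463 and a Spearman coefficient of 0.471, and 72.1% had the same sign. Of 5870 genes that passed in both marks, 85% changed in the same direction: 2251 were higher in both and 2739 lower in both, where independent calls give 1222 and 1671. Genes that changed in opposite directions numbered 469 with 5mC higher and 411 with 5mC lower, where independent calls give 1517 and 1347. Among these, chosen after their values were seen, were STC1, which encodes a hormone of calcium balance (5mC 0.73, 5hmC −0.71), ATMIN, which encodes a cofactor of the ATM kinase (0.77, −0.97), and the death receptor gene FAS (−0.71, 0.67). Of the listed 5mC regions, 67.8% (44414; 95% Wilson interval 67.41 to 68.13) overlapped a 5hmC region by at least 1 base, and 14.3% of 5hmC regions (46863) overlapped a listed 5mC region. Across 47289 overlapping pairs r was 0.78 and the Spearman coefficient 0.679, and 91.9% had the same sign; of 22380 pairs called in both marks 98.2% did. Neither genes nor regions are independent replicates, and both marks of a replicate came from the same DNA preparation. With each mark taken from 1 preparation per state, the mean r over regions was 0.607 for the same and 0.611 for different preparations. Because the 5mC list was selected for a difference between the states, these shares do not describe the genome.

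**Figure D5:**
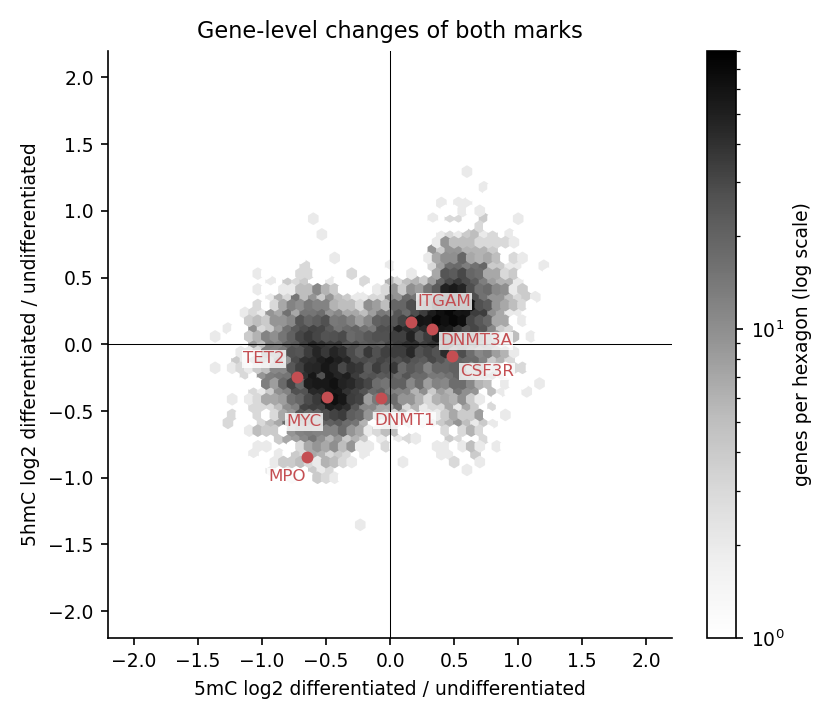
Log2 fold change (differentiated over undifferentiated, TMM scaling, n = 3 per state) of 5mC (x axis) and 5hmC (y axis) for genes within ±2, as hexagons shaded by gene count on a log scale, with 7 named genes in red. The changes correlated at r = 0.463 over 12329 genes; MPO lies at −0.65 and −0.84 and DNMT3A at 0.33 and 0.11.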

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

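TMM on strong regions only, totals of regions below the 99th percentile, adjustment over listed 5mC regions only, and the scalings and left-out libraries for gene lists were added after the data had been seen; the other alternatives were planned. A GC offset, alone or with the replicate block, and exon and intron classes were not run, because no genome of this build was used here. The 5hmC and 5mC regions named in the results kept direction and call in all alternatives run for them. DESeq2 size factors, no filter and adjustment over listed regions (65534 5mC regions) left the counts of changed regions within 1.5 times those reported. Replicate numbers do not pair the states: after removing state means, libraries with the same number correlated at 0.0113, 0.0056 and −0.0098 for 5mC and at 0.0005, −0.0994 and −0.105 for 5hmC, and not every library correlated best with its own number. With a replicate block 47248 5mC and 140424 5hmC regions changed, and 1 5hmC list passed instead of 2, the calcium list missing the threshold (adjusted p = 0.0529). In simulated data with few changed regions, 2% of 1.5-fold changes in single 5hmC regions were recovered; how far depth limits the real data, where many regions changed, was not tested.

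At a threshold of 0.01, 17764 5mC and 94718 5hmC regions and 535 and 1329 higher island regions passed, fewer by construction. DESeq2's Wald test called 3408 and 66484 regions, 194 and 1044 higher island regions, 60 lower 5hmC and 13 lower 5mC island regions, and 16 of 21 long 8q24 regions for 5mC and 2 for 5hmC. Without TMM, 82 and 1005 island regions were higher and 6 long 8q24 5hmC regions passed; with TMM on strong regions these numbers were 42, 610 and 8, and with totals below the 99th percentile 703 5mC island regions were higher. By the deposited distance, 2117 5mC and 4926 5hmC genes passed within 2 kb of gene starts, where fewer regions count. Leaving out 1 library gave 29074 to 30539 5mC regions, 102884 to 168731 5hmC regions, 721 to 808 and 1491 to 2620 higher island regions, 0 to 3 long 8q24 5hmC regions, and 1 to 2 5hmC lists. The lower 5mC island regions then numbered 80 to 95, and the lower 5hmC ones 111 without undifferentiated replicate 1 and 138 without differentiated replicate 3. With an estimated correlation 0 lists passed. The correlation of the marks was 0.7802 over regions, 0.4345 to 0.445 without a replicate number, and 0.43, 0.415 and 0.389 over genes without shared DNA, where 5hmC came from 1 preparation per state; with the stricter overlap rule 67.2% of 5mC regions overlapped. Except where stated, the cause was not tested.

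For 5mC, the top 1% of regions of a library held 46.4% to 47% of listed counts in undifferentiated and 53% to 54% in differentiated libraries. For 5hmC these shares were 25.8% to 27.7% and 30.4% to 37.2%. Scaling by totals, like chromosome shares, therefore moves the other regions down in differentiated libraries. Directions turned as follows, and how much of each turn came from this or from another cause was not tested. Within 2 kb of gene starts, 5hmC turned at DKK2 (−0.22), EIF4EBP1 (0.021), ITGAM (−0.56) and WASF2 (0.0087), and 5mC at HOXA3 (−0.63) and ITGAM (−0.68). Without TMM, ITGAM turned for 5hmC (−0.039) and 5mC (−0.15). With TMM on strong regions, 5hmC turned at DNMT3A (−0.18), ITGAM (−0.13), MFNG (−0.032), NCAM1 (−0.018) and PAX5 (−0.0049) and for calcium genes (adjusted p = 0.978), and 5mC turned at DNMT3A (−0.018), ITGAM (−0.19) and NFATC1 (−0.029). Below the 99th percentile of counts, log2 ratios of chromosome shares turned for 5hmC at chromosomes 5 (0.042), 6 (0.019), 8 (0.069), 9 (0.0095), 11 (0.018), 13 (0.057), 14 (0.018), 16 (−0.054) and 20 (0.00802), and for 5mC at 5 (0.11), 6 (0.072), 7 (0.039), 8 (0.16), 9 (0.069), 14 (0.049), 16 (−0.064) and 18 (0.082). So did 2 shares that had not been separated between the states, chromosome 13 for 5mC (0.172) and 18 for 5hmC (0.0818).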

Other observations

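The densest windows of both marks lay mostly next to centromeres. The chromosome 16 window at 46000001 to 47000000, which led for 5mC, was also the one of the 10 densest 5hmC windows with the largest rise (1.1 ± 0.151 on the log2 scale, SD, n = 3 per state), and the chromosome 10 window at 42000001 rose by 0.83 ± 0.181. Similar rises lay at chromosome 21 from 10000001 (5mC 0.64, 5hmC 0.74) and at chromosome 2 from 89000001 (0.62 and 0.77). Most of the chromosome 2 window was 1 region, 89848401 to 89880400, nearest to MIR4436A. In differentiated cells it held 16600 of 17300 CPM for 5mC and 14300 of 14500 CPM for 5hmC. The chromosome 1 window from 1000001 to 2000000 fell for both marks (5mC −0.43 ± 0.0658, 5hmC −0.33 ± 0.106).

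Genes with opposite changes included SRFBP1, which encodes a binding protein of the serum response factor (5mC 0.97, 5hmC −0.69), CYP4X1, a cytochrome P450 gene (0.69, −0.74), and the histone genes HIST1H4C (0.79, −0.91) and HIST1H4D (0.82, −0.70). These were chosen after their values were seen.

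The tests below were chosen only after the results were seen, except those of GC content and of other splits of the libraries for gene lists. The 5mC and 5hmC changes went in the same direction in overlapping regions. Noise shared by the aliquots of a DNA preparation is argued against, since the mean r over regions was 0.611 for marks from different preparations and 0.607 for the same preparation. Long stretches of differing DNA dosage are argued against as the whole cause, since of neighbouring 5mC regions up to 1 kb apart 76.4% had the same sign, fewer than the 91.9% of overlapping regions of the marks. Capture that does not separate the marks fully, or a change of both marks on the same DNA, stays open and was not tested.

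The long 8q24 regions were lower in differentiated cells. The scaling is argued against for 5mC, where their median was at most −0.479 over 5 scalings, and a scaling moves all regions alike while all 31 other long regions were higher. Whether a background lower in some differentiated libraries caused the differences among them could not be decided, since 3 libraries allow only a comparison of ranks. The differentiated 5hmC library with the highest share of counts in its top regions was not the lowest at 8q24 (−0.0952 against the undifferentiated mean). For the fall common to all 3, background and biology cannot be told apart with 0 input or control libraries analysed. A candidate explanation is that the DNA held fewer copies of the segments, most so in preparation 1, which was picked because it was lowest there. Its 5hmC level lay at −0.369 against the other 2 differentiated preparations. Of 1277 other windows of at least median density in both marks, each with its own lowest 5mC preparation, 0 lay as low in 5hmC (lowest −0.351). This was a difference shared by both marks of a preparation; whether it lay in copies, in the marks or in other properties of the DNA was not separated.

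Under TMM scaling, CpG island regions were more often higher than lower in differentiated cells. A rise of all dense regions is argued against for 5hmC islands under a log2 density of 2, which exceeded other regions of like density by 0.267 or more, and in the selected 5mC list for islands under 1.5, which exceeded others by 0.779 or more. It may account for the median change of denser islands, which differed from other regions by −0.066 at most for 5hmC and −0.076 at most for 5mC. It is argued against as the whole cause of their direction. At a 5hmC log2 density of 2 to 3, 93.4% of islands and 71.2% of other regions lay above 0, and above 3, 98.1% and 91.1%. In the selected 5mC list these shares were 93.8% and 70.1% at 1.5 to 2, 96% and 86.6% at 2 to 3, and 95.9% and 64.7% above 3. The scaling may account for the balance itself, since only 42 5mC islands were higher and 173 lower with TMM on strong regions. These 5mC counts are partly set by the selection of the list under a scaling close to TMM. For 5hmC, 610 islands were higher and 614 lower. The scaling is argued against for the difference of islands from other regions, because a scaling moves all regions alike. With TMM on strong regions the island median was 0.10 against −0.07 for all listed 5mC regions, and 0.07 against −0.34 for all 5hmC regions. GC content cannot be told apart from an island effect, since 0 regions had a GC value. A rise of both marks at islands during maturation stays open as a hypothesis.

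The 6 libraries of a mark can be split into groups of 3 in 10 ways, too few for a share under 0.05. By edgeR, the real split gave 47662 changed 5mC regions and 10645 5mC genes where the highest other split gave 0 of each (138 to 194 regions at an unadjusted p under 0.05). Because the 5mC list was selected for the real split, this outcome was fixed in advance. For 5hmC it gave 164904 regions and 10523 genes where the highest other gave 0 (1831 to 18392 regions unadjusted); in each case 1 split reached the real count. For gene lists the real split gave 2 5hmC lists, with 0 as the highest other, and 0 5mC lists, with 1 as the highest other, so that all 10 splits gave as many.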
